A study of Vibrio parahaemolyticus with 6 samples.

How the data were processed

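Total RNA of Vibrio parahaemolyticus strain CGMCC1.1614 was made into directional libraries from 3 µg of RNA per sample and sequenced in paired-end mode on an Illumina HiSeq instrument, per the labels' protocols. CASAVA 1.8 and HTSeq 0.6.1 were used, per the submitters' processing notes, which do not give their roles. The aligner, the genome build and the gene annotation are not given in the sources used here. The authors deposited a table of FPKM values for each sample, per the file headers, with 1 identifier per line. FPKM divides each count by gene length and by the library total, so a few very abundant RNAs lower the values of all other genes in that library. Samples were grouped by the treatment label into 3 control and 3 BITC samples. Control replicate 1 listed 4988 identifiers and the other 5 files 5013. The 25 identifiers missing from control replicate 1 reached at most 7.52 FPKM elsewhere and were left out of the tests.

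The low FPKM values of a gene are whole multiples of a fixed step, so read counts, gene lengths and library totals were worked out from the decimals. All 27653 values above 0 passed as whole counts within 0.0001 reads. Gene lengths were searched for so as to give whole counts, and a gene without a fitting length would also pass, so this was no independent check. The counts summed to 99.9% of each library total. Of the lengths of locus tags, 99.9% were multiples of 3, so they are coding lengths. On simulated data over 1504 genes the method found all 6 totals. Of 8235 counts above 0 for which it gave a value, 99.0% were exact. Of 34 rows with an rRNA prefix, 32 stood at 0 in every file. These counts served for depth, for comparing libraries, and for limma-voom as an alternative.

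The design fixed before the data were examined had foreseen counts, with limma on log2(value + 1) in their place if the files held FPKM. The files held FPKM, so limma 3.58.1 in R 4.3.3 was fitted to log2(FPKM + 1) with a mean trend in the variance, over the 4560 identifiers of mean FPKM of at least 1, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The fit was also run on simulated data with 200 changed genes among 4560 for this comparison. There it recovered 55.6% of genes changed 2-fold, 95% of those changed 4-fold, 99% at 8-fold and 99.6% at 16-fold, with 5.31% false calls. These shares hold for the simulated data only and may be lower in the real libraries. In the real data, locus tags VP1677 and VP1678 differed 5.69-fold and 4.88-fold and were not called (limma adjusted p = 0.118 and 0.111). An absence of calls therefore does not exclude changes of 4-fold or more. Lists were tested with camera in limma at a preset inter-gene correlation of 0.01, with an estimated correlation and fry as alternatives, for lists of at least 5 tested genes. A list moved by 1 log2 unit was called in 20 of 20 simulated runs, and 2 lists were called with no change over 20 runs, also with independent genes. Means over lists were compared by an exact permutation test, two-sided. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 was used for the counts and figures.

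Fixed before the data were examined were 44 gene lists, the rule for named genes and the main alternatives. The files do not pair identifiers with names and no reference genome was used here, so 35 lists defined by gene names or products were not matched. The other 9 were matched by locus tag ranges of the species' reference strain, set from general knowledge and not checked against an annotation. Names and products in those 9 lists were not matched either. The rule named the 10 risen and 10 fallen genes of known product with the largest change, or, with no product known, 2 identifiers that rose and 2 that fell, at a mean FPKM of at least 10 and with groups that do not overlap. No gene passed the threshold, so the rule was applied without it. Alternatives covered scaling, low-value filters, the pseudocount, limma-voom, leaving out each library, the replicate block, rows of structural RNA and the threshold. Alternatives with both outlying libraries left out, library weights, all rows outside the locus tags left out of the totals, near-identical libraries averaged, and scaling combined with limma-voom or a left-out library were added after the data were seen, as was the camera test between the chromosomes.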

Results

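RNA was sequenced from cultures of the food-borne pathogen Vibrio parahaemolyticus, strain CGMCC1.1614, grown with or without benzyl isothiocyanate (BITC), an antibacterial compound of cruciferous plants. BITC was given at 1/8 of its minimal inhibitory concentration, the lowest concentration that stops visible growth. There were 3 control samples and 3 BITC samples. The labels do not say whether these were separate cultures, so the p-values measure the spread between these samples, which may be technical. The files listed FPKM (fragment counts scaled to gene length and library total) for 5013 identifiers, most of them VP and VPA locus tags, the gene numbering in which VP marks chromosome 1 and VPA chromosome 2. The library totals behind the FPKM, worked out from the decimals, were 3298786, 3358536 and 3380920 counts in control replicates 1, 2 and 3 and 3317856, 3206269 and 2861635 in BITC replicates 1, 2 and 3. A gene of 1 kb with a single count stood at 0.296 to 0.349 FPKM across the 6 libraries. The files do not pair the identifiers with gene names or positions, so genes are given by identifier.

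Short features outside the locus tags took a large share of each library. The features Novel00001, Novel00004, Novel00009 and sRNA00039, of 264 to 442 nt, together held 41.0% ± 3.46 of the counts in control and 44.9% ± 1.28 with BITC (SD, n = 3 each). The locus tags held 58.5% ± 3.43 in control and 54.7% ± 1.22 with BITC. sRNA00039 stood at 10.8% ± 2.23 of the counts in control and 15.2% ± 2.49 with BITC, and Novel00009 at 10.8% ± 1.54 and 13.9% ± 1.30. In limma neither passed, with adjusted p = 0.339 for sRNA00039 and 0.410 for Novel00009. Novel00001 held 4.21% to 4.75% of the counts in 5 libraries and 0.718% in BITC replicate 3. These features were singled out after their values were seen.

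**Figure D1:**
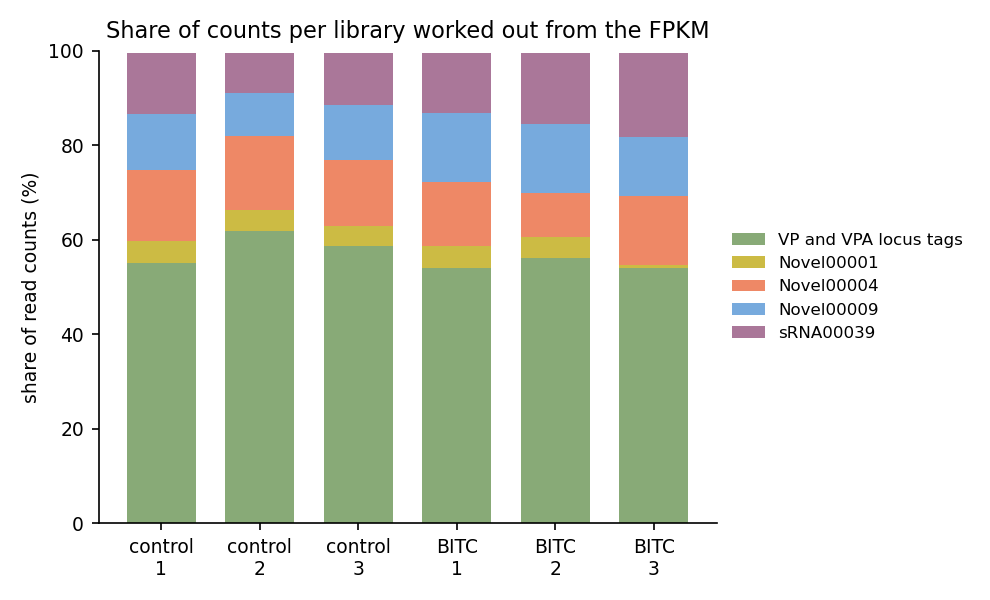
Share of read counts (percent, vertical axis) held by the VP and VPA locus tags and by 4 abundant short features in each of the 6 libraries. The locus tags held 54.0% to 61.9% of the counts, and Novel00001 was at 0.718% in BITC replicate 3 against 4.21% or more in the other libraries.

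The libraries did not separate fully by treatment. On the first principal component, with 35.4% of the variance, control replicates 2 and 3 lay at 24.4 and 18.5 and BITC replicates 1 and 2 at -20.5 and -21.2, while control replicate 1 and BITC replicate 3 both lay at -0.61. BITC replicate 3 stood apart on the second component, with 30.5% of the variance. Across 4560 genes, which are not independent replicates, Pearson's r was 0.982 between control replicates 2 and 3 and 0.980 between BITC replicates 1 and 2. The lowest r was 0.950, between BITC replicates 1 and 3, and BITC replicates 2 and 3 also stood at 0.950. BITC replicate 3 was slightly closer to control replicates 1, 2 and 3, at 0.958, 0.952 and 0.955. Control replicate 1 stood at 0.968 and 0.971 with control replicates 2 and 3, and at 0.971 and 0.970 with BITC replicates 1 and 2. The counts of the close pairs, control replicates 2 and 3 and BITC replicates 1 and 2, still differed by more than sampling noise. Their chi-square per degree of freedom over locus tags was 2.68 and 2.46, against 12.9 to 40.4 for the other pairs of libraries. The median chi-square of a locus tag was 0.771 and 0.749, against 2.05 to 4.45. The level of this median under sampling noise alone was not worked out, so a value under 1 does not mean noise alone. Repeat preparations of the same culture could also exceed sampling noise, so these values do not show that the close pairs are separate cultures. All 6 libraries were counted separately, which was not tested.

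**Figure D2:**
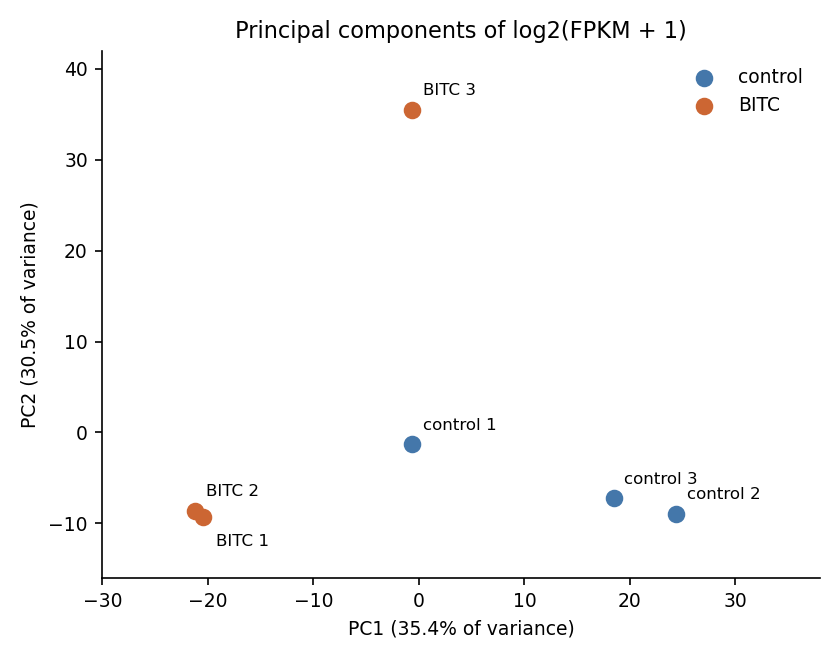
Principal components 1 and 2 of log2(FPKM + 1) over 4560 genes, with the share of variance on each axis and a point for each of the 3 control and 3 BITC libraries. Control replicate 1 and BITC replicate 3 lie at -0.61 on the first component, between the other control and the other BITC libraries.

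The design held a single comparison, which asked which genes changed in expression when BITC was added. Among the larger differences were those of neighbouring genes in the type III secretion system 1 region, the gene cluster for a needle complex that injects proteins into host cells. VP1677 in that region stood at 22.9 ± 3.69 FPKM in control and 152 ± 79.6 with BITC (SD, n = 3 each), a log2 fold change of 2.51 ± 0.43 (SE). VP1678, next to it, stood at 36.9 ± 2.60 and 202 ± 93.5 FPKM, a log2 fold change of 2.29 ± 0.37. In the polar flagellum region, which encodes the filament used for swimming, VP2248 stood at 58.3 ± 13.5 FPKM in control and 26.1 ± 3.67 with BITC, a log2 fold change of -1.11 ± 0.22. In all 3 genes every BITC library lay on the same side of every control library, but across the genome none of them passed, with limma adjusted p = 0.118, 0.111 and 0.118.

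Over 4560 tested genes, limma called 0 genes changed at an adjusted p under 0.05, and limma-voom on the recovered counts also called 0. The lowest adjusted p was 0.079. At an unadjusted p under 0.05 there were 843 genes in limma, 115 higher and 728 lower with BITC, where chance gives 228, and 864 in limma-voom. With 1 library left out the limma count ranged from 442 (68 higher, 374 lower, without control replicate 2) to 1114 (without control replicate 1 or without BITC replicate 3). The groups did not overlap in 24.2% of genes, 219 higher and 886 lower with BITC, where chance gives 10%. Both chance values are averages, and genes do not vary independently. The other 3 against 3 splits of the libraries gave 48 to 639 genes at an unadjusted limma p under 0.05. Overlap was judged without scaling, so the shift of the median gene, given next, is part of it. The median gene was lower with BITC by a log2 fold change of -0.18. With median-of-ratios scaling, which sets the median near 0, limma again called 0 genes, and of 693 genes at an unadjusted p under 0.05, 332 were higher and 361 lower. The count of called genes depended on 2 libraries and on the scaling. It was 159 (9 higher, 150 lower) without control replicate 1, 67 (23 higher, 44 lower) without BITC replicate 3, 1245 (231 higher, 1014 lower) without both, and 0 without any other single library. Both were left out because they stood apart, which narrows the spread within groups that the p-values measure. Averaging the close pairs instead called 0 genes (lowest limma adjusted p = 0.708). This left 2 against 2, with more weight on each outlying library and less to estimate the spread from, so few calls could be made. With median-of-ratios scaling the count of called genes was 0 without control replicate 1. Without BITC replicate 3 it was 91, with most of them on the higher side (57 higher, 34 lower).

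The identifiers with the largest differences, among locus tags of mean FPKM of at least 10 whose groups did not overlap, were VP2388 and VP1677 on the higher side and VP0779 and VP0371 on the lower side. VP2388 had a log2 fold change of 3.19 ± 1.67 (SE, limma adjusted p = 0.356). Its level was 5.30 ± 1.01 FPKM in control and 468 ± 792 with BITC (SD, n = 3 each), and it rested on BITC replicate 3, at 1382 FPKM against 7.34 and 15.2 in the other BITC libraries. Without BITC replicate 3 its log2 fold change was 0.90. VP1677 had 69 to 91 counts per control library and 181 to 698 per BITC library, and without BITC replicate 3 its log2 fold change was 3.06, with limma adjusted p = 0.000852. It did not pass without any other single library, where adjusted p ranged from 0.0547 to 0.451. VP0779, at 17.2 ± 3.47 and 6.33 ± 6.05 FPKM, and VP0371, at 17.9 ± 2.34 and 6.27 ± 3.96 FPKM, rested on 0 to 8 counts per library. VP0779 lies within the polar flagellum region. Their log2 fold changes were -1.94 ± 0.85 and -1.51 ± 0.38, with limma adjusted p = 0.274 and 0.135, and that of VP0779 was -0.82 without BITC replicate 2 and -3.06 with a pseudocount of 0.1.

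**Figure D3:**
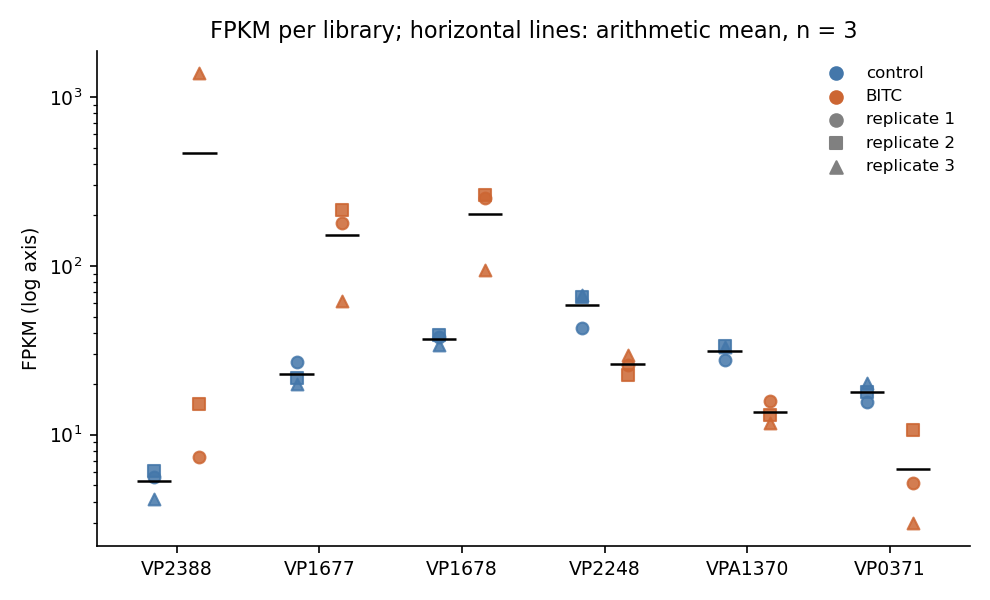
FPKM per library (log axis) of 6 locus tags in the 3 control and 3 BITC libraries, with a marker per replicate number and a horizontal line at the arithmetic mean. All 6 locus tags have all BITC libraries on one side of all control libraries. VP2388 reaches 1382 FPKM in BITC replicate 3 alone, with 7.34 and 15.2 in BITC replicates 1 and 2.

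Of 44 gene lists, 9 could be matched to the files through locus tag ranges. Over all genes adjusted, 0 members of any of the 9 lists changed, and camera called 0 lists at an adjusted p under 0.05 (adjusted p of 0.502 or more with an estimated correlation). The count of members depended on the outlying libraries. Without control replicate 1, 2 polar flagellum, 1 type III secretion system 1 and 1 type III secretion system 2 members fell. Without BITC replicate 3, 3 type III secretion system 1 members rose and 1 type III secretion system 2 member fell. Without both, 1 polar flagellum member rose and 19 fell, 3 type III secretion system 1 members rose and 1 fell, 1 type III secretion system 2 member rose and 10 fell, and 1 member each of the type VI secretion system 2 and f237 lists rose. Leaving out both narrows the spread within groups by the choice of libraries. The counts adjusted over the list alone, given for each list, were 0 in all 9 lists when the near-identical libraries were averaged, which left 2 against 2. With the medians below, the shift of the median gene by -0.18 is part of each value.

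In the type III secretion system 1 region, 31 genes were tested, and their median log2 fold change was -0.06, which is 0.12 above that of all genes. Relative to all genes it was 0.02 without control replicate 1 and turned to -0.03 without BITC replicate 3. The mean was 0.09, so median and mean differed in sign, and the median was 0.11 with median-of-ratios scaling. The library means of the list did not separate the groups (two-sided exact permutation p = 0.4). The camera test placed the list above other genes without passing (adjusted p = 0.119, and adjusted p = 0.502 with an estimated correlation). Adjusted over the list alone, 4 members rose and 1 fell. VP1677 and VP1678 were among the 4, both with adjusted p = 0.00669 over the list. The number that rose was 2 or 3 when any single library was left out. With 1 library left out, the camera adjusted p ranged from 0.0295, a call, without BITC replicate 2 to 0.310 without BITC replicate 3. Camera also called the list over its 6 genes of mean FPKM of at least 10 (adjusted p = 0.00758). Both calls were lost with an estimated correlation (adjusted p = 0.646 and 0.185).

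The polar flagellum region had 51 tested genes, 8 with a higher and 43 with a lower mean with BITC. The mean log2(FPKM + 1) of the list was 4.88 ± 0.098 in control and 4.53 ± 0.131 with BITC (SD, n = 3 each). Every BITC library lay below every control library (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). The lateral flagellum and type III secretion system 2 lists gave the same p. The median log2(FPKM + 1) of all genes separated alike, at 5.05 to 5.26 in control and 4.86 to 4.95 with BITC, so this separation is not particular to the list. The median log2 fold change of the list was -0.25, which is -0.07 relative to all genes. Camera did not call the list (adjusted p = 0.119, and adjusted p = 0.676 with an estimated correlation). Over its 39 genes of mean FPKM of at least 10 it was called (adjusted p = 0.00758), and not with an estimated correlation (adjusted p = 0.434). Adjusted over the list alone, 1 member rose and 4 fell, VP2248 among them (adjusted p = 0.0443 over the list). With median-of-ratios scaling 1 rose and 1 fell. The number that fell was 6 without control replicate 1, 15 without BITC replicate 3, and 0 without any one of the other 4 libraries.

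In the type III secretion system 2 region of chromosome 2, the cluster linked to enterotoxicity, 48 genes were tested, 10 higher and 38 lower with BITC. Their median log2 fold change was -0.19, or -0.01 relative to all genes, and camera gave adjusted p = 0.466. Leaving out 1 library gave medians of -0.27 (without BITC replicate 3) to -0.12 (without BITC replicate 1). Relative to all genes these ranged from -0.07 (without BITC replicate 3) to 0.04 (without control replicate 1). Adjusted over the list alone, 0 members rose and 1 fell, VPA1370, at 31.4 ± 3.38 FPKM in control and 13.5 ± 2.03 with BITC (SD, n = 3 each), a log2 fold change of -1.16 ± 0.19 (limma adjusted p = 0.0140 over the list and 0.111 over all genes). No member fell without control replicate 2, control replicate 3 or BITC replicate 2, where the count was 0, and 2 fell without BITC replicate 3. VP1678, VP2248 and VPA1370 were chosen for the text after their values were seen.

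In the other 6 lists 0 members changed with all 6 libraries weighted equally, also when adjusted over the list alone. With library weights, members of the lateral flagellum, type VI secretion system 2, capsule and f237 lists were called over the list alone. The lateral flagellum region, which encodes the filaments used for swarming, had 37 tested genes, a median log2 fold change of -0.05 and camera adjusted p = 0.177. The mean log2(FPKM + 1) of this list was 2.74 ± 0.013 in control and 2.62 ± 0.044 with BITC (SD, n = 3 each). The contact-dependent type VI secretion systems 1 and 2 had 25 and 23 tested genes, medians of -0.05 and -0.14 and camera adjusted p = 0.177 and 0.492. The 8 tested genes in the vibrioferrin region, for uptake of iron by a siderophore, had a median of -0.11 (camera adjusted p = 0.597), and the 8 of the capsule and exopolysaccharide region -0.18 (0.611). The 6 tested genes of the f237 prophage region had a median of 0.16 (camera adjusted p = 0.127) and a mean of 0.02. With median-of-ratios scaling the medians of the lateral flagellum, type VI secretion system 1 and iron lists turned to 0.13, 0.13 and 0.04. In 5 of these 6 lists, all but f237, the median was below 0 while camera placed the list above other genes, since it compares with all genes, whose median was lower still or nearly the same. For the iron and type VI secretion system 2 lists this placement turned to below other genes without BITC replicate 3, with medians of -0.13 and -0.19 relative to all genes. Single libraries moved these medians. Leaving out 1 library gave -0.34 (without BITC replicate 3) to 0.01 (without BITC replicate 2) for the iron list, and -0.40 to -0.03 without the same libraries for type VI secretion system 2. For type VI secretion system 1 the median was -0.16 without BITC replicate 3 and 0.02 without control replicate 1. It ranged from -0.24 (without control replicate 2) to -0.04 (without BITC replicate 1) for the capsule list and from 0.09 (without control replicate 3) to 0.21 (without control replicate 1) for f237. For the lateral flagellum it ranged from -0.09 (without BITC replicate 2) to -0.0055 (without BITC replicate 1). Over genes of mean FPKM of at least 10, camera called the lateral flagellum and type VI secretion system 1 lists (adjusted p = 0.0498 each, and adjusted p = 0.434 each with an estimated correlation). The library means of the type VI secretion system 2 and iron lists had a wide spread with BITC, with SDs of 0.373 and 0.334 log2 units against 0.105 and 0.101 in control.

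**Figure D4:**
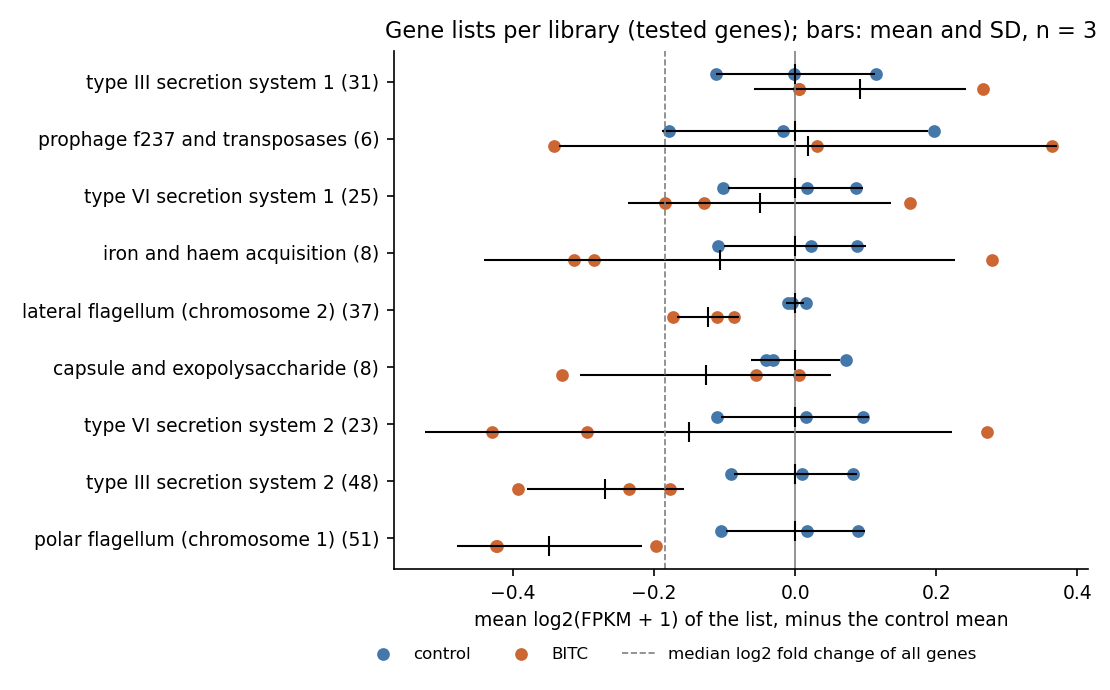
Mean log2(FPKM + 1) of each gene list in each library, minus the mean of the 3 control libraries (horizontal axis), for 9 lists with the number of tested genes in brackets. Vertical ticks and horizontal bars show the mean and SD (n = 3), and the dashed line the median log2 fold change of all genes at -0.18. The 3 BITC libraries lie below the 3 control libraries in the polar flagellum, lateral flagellum and type III secretion system 2 lists.

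The chromosomes were compared through the identifier prefix. The median log2 fold change was -0.21 over 2893 tested VP genes and -0.15 over 1614 VPA genes. At an unadjusted p under 0.05 there were 68 VP genes higher and 554 lower with BITC, and 47 VPA genes higher and 170 lower. A camera test of the VPA genes against the VP genes gave p = 0.0404, and p = 0.203 with an estimated correlation. With 0 genes called, the share of changed genes per chromosome could not be compared by Fisher's exact test.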

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

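The alternatives with weights, with both outlying libraries left out, with near-identical libraries averaged and those that combine scaling with limma-voom or a left-out library were chosen after seeing the data. The count of 0 genes held under median-of-ratios and upper-quartile scaling, both low-value filters, a pseudocount of 0.1, limma-voom, an adjusted p under 0.01, and with structural RNA rows or all rows outside the locus tags left out of the totals. At an adjusted p under 0.1 there were 2 genes. Leaving out 1 library gave 0 to 159 changed genes, 0 to 23 higher, 0 to 150 lower, 0 to 101 changed at least 2-fold and 0 to 1 lists. The extremes came without control replicate 1 (159 changed, 9 higher, 150 lower, 101 at least 2-fold) and without BITC replicate 3 (67, 23, 44 and 53). Of these, 14 genes were shared. Without both libraries together, a choice that narrows the spread within groups, 1245 genes were changed (231 higher, 1014 lower, 330 at least 2-fold). Averaging the near-identical libraries instead gave 0 (lowest limma adjusted p = 0.708), with 2 against 2 left and more weight on each outlying library. Library weights in limma gave 1448 (267, 1181 and 311), with weights of 0.352 for control replicate 1 and 0.230 for BITC replicate 3, and limma-voom with library quality weights gave 1325 (219, 1106 and 305). Of the 1245 and 1448 genes, 1119 were shared. Limma-voom with median-of-ratios scaling called 1 gene, higher and at least 2-fold. Median-of-ratios scaling without BITC replicate 3 gave 91 (57 higher, 34 lower, 55 at least 2-fold), and without control replicate 1 it gave 0. The cause of these differences was not tested, apart from the fewer or down-weighted libraries.

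Gene lists were called in 4 cases with a mean FPKM of at least 10, where fewer genes entered (polar flagellum and type III secretion system 1, adjusted p = 0.00758 each, lateral flagellum and type VI secretion system 1, 0.0498 each), and none of the 4 with an estimated correlation (adjusted p of 0.185 or more). Averaging the near-identical libraries called 1 list (type III secretion system 1, adjusted p = 0.0148, and 0.751 with an estimated correlation), fry in either direction called 3 (lowest adjusted p = 0.00125), and 3 lists had a called member adjusted over the list alone, which averaging the near-identical libraries ended in all 3. The iron and type VI secretion system 2 lists reversed direction under a few alternatives, never with a call. With 1 library left out, their adjusted p ranged from 0.259 to 0.682 and from 0.105 to 0.682, and direction reversed without BITC replicate 3 (0.520 and 0.366). The direction was also reversed without the 2 outlying libraries together (adjusted p = 0.627 for both) and, at adjusted p = 0.510 and 0.476, with median-of-ratios scaling without BITC replicate 3. The iron list also reversed under limma-voom with library quality weights (0.780), and both lists reversed under library weights in limma (0.667 and 0.911).

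Both groups are numbered 1 to 3, and a replicate block gave 0 genes and 0 lists, with 761 genes at an unadjusted p under 0.05. Deviations from the group means correlated at 0.019, -0.045 and 0.020 between libraries of the same number, so the numbers do not pair the samples. The fit planned for deposited counts was not run, and limma-voom was the only count model. Library totals alone equal the FPKM scale used. The chromosome share has no value with 0 genes called. Depth limits short and low genes: VP0371, of 117 nt, had 6 to 8 counts per control library and 1 to 4 per BITC library.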

Other observations

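The test on the number of genes called at an adjusted p under 0.05 in other splits was chosen only after the result was seen, and so were the count of blocks and the correlations of neighbouring genes between control libraries. Genes that lie next to each other tended to differ together. There were 46 blocks of 3 or more consecutively numbered locus tags with the same direction and an unadjusted limma p under 0.05, 5 higher and 41 lower with BITC, holding 160 genes. When directions were shuffled among genes 200 times, the median was 14 blocks and the highest 24. Of the 5 higher blocks, that from VP1677 to VP1679 in the type III secretion system 1 region had the largest mean log2 fold change, 2.08. The longest blocks held 6 genes, both lower with BITC.

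For VP1677 to VP1679, a candidate explanation is that neighbouring genes change together, as they would within operons. Over 4281 pairs of consecutive locus tags, which are not independent, the log2 fold changes correlated at 0.21 (Pearson's r), above every one of 10000 shuffles, whose highest was 0.06 (permutation p = 1e-04, the smallest they can give). The same correlation was 0.05 between control replicates 2 and 3, and 0.17 for control replicate 1 against them. Since control replicate 1 stands apart and its label may be wrong, these values do not settle whether neighbours differ together without BITC. A response of this region to BITC stays open as a biological hypothesis.

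BITC replicate 3 stood apart from BITC replicates 1 and 2: 279 of 3422 locus tags of mean FPKM of at least 10 were over 2-fold away from the mean of those libraries, against 36 between them. Lower depth does not account for it: with every library thinned to the smallest total the gap in correlation was 0.0289 ± 0.00059 (SD of 20 draws), against 0.0301 before. Removing a trend with gene length left 281 genes, and scaling to the locus tags by median of ratios, which removes the share of the abundant RNAs, left 277. A swap of the labels of control replicate 1 and BITC replicate 3 did not meet the limits on position set before the test. Over 273 genes that differed 2-fold or more between the other controls (0) and the other BITC libraries (1), the median position was 0.571 (95% bootstrap interval 0.512 to 0.621) for control replicate 1 and 0.685 (0.556 to 0.778) for BITC replicate 3. Both lay past the midpoint on the BITC side, which goes against a swap for BITC replicate 3 but not for control replicate 1. The genes were chosen by the other libraries, which draws a library left out of that choice inward, so a swap is not excluded. BITC replicate 3 also correlated slightly better with each control than with the other BITC libraries. What remains open is a separate culture, day or library batch, which the labels do not give. A wrong label of either library or of both also remains open.

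The median gene was lower with BITC, at a log2 fold change of -0.18. The abundant RNAs outside the locus tags, which took a larger mean share with BITC, may account for part of this, since leaving them out of the totals gave -0.10, and -0.13 to -0.07 when any single library was left out as well. They do not account for all of it by this measure. Abundant genes among the locus tags were not tested separately, and a change in total RNA per cell cannot be read from these relative values.

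The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 843 genes at an unadjusted p under 0.05, 1 of the 10 splits gave as many, and the highest other split gave 639. At an adjusted p under 0.05 the real split gave 0 genes, a count that all 10 splits reach by construction, so it says nothing about chance. The highest other split gave 3. Both highest values came from the split that put control replicate 1 with BITC replicates 1 and 2. That is the grouping that a swap of the labels of control replicate 1 and BITC replicate 3 would give.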
